A study of Mus musculus with 109 samples.

How the data were processed

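Total RNA from mouse lung was hybridised to 109 single-colour Illumina bead arrays, 1 array per sample. Per the labels, mice breathed smoke from research cigarettes, main-stream and side-stream mixed, on 5 days a week for 6 months, or filtered air, and RNA was extracted with a commercial kit. The labels place every array in 1 of 8 groups by strain, genotype and exposure: wild type of the strains C57BL/6J and NZW/LacJ, Hhip+/- and Fam13a-/-. The sample labels write C57BL6 and NZWLacJ, and the full strain names are those of the series text. The titles of the 14 NZW/LacJ arrays name C57, while their strain label names NZWLacJ; the strain label was used. No label gives the sex, the litter or the slide, and none says that the arrays come from separate animals, so the p-values measure the spread between these samples.

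The authors deposited a table of probe intensity, with a detection p-value for each of 25697 probes on each array. Per the file headers and the values, these intensities were neither normalized between arrays nor background-subtracted; the scanner software and its steps are not given in the sources used here. The authors also deposited normalized values on a log2 scale, whose method is not given in the sources used here. Each of its 109 columns correlated best with the intensities of its own array, with a lowest correlation across probes of 0.991, its column medians ran from 7.21 to 7.22, and at any rank the columns differed by at most 0.0089, as after quantile normalization. These values are compressed near background and are not centred per probe; how they were background-corrected stays unknown, and they served only as an alternative.

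The main values were made from the deposited intensities with the neqc function of limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8, for reading. Its steps are normexp background correction, with the background inferred from the detection p-values, an offset of 16, quantile normalization and log2. A probe was kept when its detection p was below 0.01 on at least 6 arrays, the size of the smallest groups, which left 15363 probes. Platform annotation gives 23978 probes 1 gene symbol, none several and 1719 no symbol. Symbols were updated through the gene identifier for 23962 probes and through the transcript accession for 9, using a RefSeq gene table of the GRCm38.p6 assembly; 7 kept the platform's symbol. That table served only for names and for which genes neighbour each other. The brightest kept probe stood for each gene, which gave 11346 genes or unnamed probes, 10286 of them with a name that the text may use. Other kept probes of a named gene had the opposite sign in 4 of 46 cases, and none of these passed the threshold. The deposited signals vary in level, with array medians from 66.1 to 144.5, and 36.0% to 53.9% of probes were detected per array, median 49.9%. The correlation between arrays reached at most 0.992, and no pair was treated as a repeat of 1 sample.

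All 8 groups entered 1 linear model of group means in limma (lmFit, eBayes, 101 residual degrees of freedom), and all 10 comparisons are contrasts in it, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. They are smoke minus air within each strain or genotype, the difference of each smoke effect from that of C57BL/6J wild type, and each air group minus C57BL/6J wild-type air. Every adjusted p in the text is from limma, or from limma's camera test for a gene list. The 39 gene lists, of pathways, lung cell types and tissues that a lung sample could carry along, were tested with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over lists within a comparison. The lists overlap in part, and Nqo1 stands in 2 of the lists described. Counts of list members past the threshold are given over all genes, and in most cases also adjusted over the list alone. Where no array of a group detected a probe, the fold is given as a bound, the bright group's mean against the mean, per array, of the higher of the lowest signal among detected probes and the probe's own signal.

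The rule for the genes named took Hhip and Fam13a always, the 12 largest rises and 8 largest falls past the threshold for smoke in C57BL/6J wild type, the 6 largest of each for the other smoke and air comparisons, the 10 smallest adjusted p for each difference of smoke effects, and up to 4 called members of each list described, at most 10 lists a comparison. Clone, predicted and locus names were counted and not named. The groups, the tests, the gene lists, this rule and most alternatives were fixed before the data were examined; alternatives chosen after seeing the data are said to be so. Draws of C57BL/6J wild-type arrays at the sizes of the smaller units, 100 each, were fitted on their own.

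The fit and the gene list test were run on simulated log2 values with the group sizes and spread of these arrays; normalization and probe choice were not simulated. Of genes simulated with a log2 change of 1, the fit called 100% for smoke in C57BL/6J wild type, 98.5% in Hhip+/-, 91.0% in Fam13a-/- and 82.1% in NZW/LacJ; with a change of 0.5 these were 88.1%, 58.2%, 35.8% and 29.9%. In the simulated differences of smoke effects, a change of 1 was called for 92.5%, 85.1% and 77.6% of genes in the same order. In each comparison 67, 67 and 66 genes were changed by 0.5, 1 and 2. Unchanged genes falsely called numbered 11, 10, 6 and 13 for smoke, 6, 6 and 8 for the differences, and 19, 7 and 7 in air. The camera test called the 1 list that was shifted and 0 of the others, of 39. The simulated genes varied independently of each other, so this does not test the preset inter-gene correlation.

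The alternatives changed background correction, scaling, the source of the values, the filter, the probe summary, the arrays in the fit, array weights, the variance model, residual components and the inter-gene correlation, or left out arrays of doubtful quality. The bound for doubtful quality, 4 median absolute deviations below the median of the within-group correlations, was first read with R's scaled deviation, then run with the unscaled one, and the scaled reading was kept as the main form of that alternative; both are reported, and the unscaled one counts as chosen after seeing the data. Among the alternatives fixed beforehand, these were not run: a Y-linked covariate, since Kdm5d and Eif2s3y were detected on 0 arrays and Uty on 21, and the slide as a block, since no slide is given. Arrays whose strain went against the label were found after seeing the data. The position of an array is the median, over strain-specific genes, of its place between the group medians of the other exposure, with 0 at C57BL/6J and 1 at NZW/LacJ. Strain-specific genes differed by at least 2 on the log2 scale between those medians, with an adjusted p under 0.05. A position below 0.25 was first asked of genes higher and of genes lower in NZW/LacJ, and then of genes lower alone, because the position on higher genes ran from -0.12 to 1.06 among the other NZW/LacJ air arrays; both forms picked the same 2 arrays. The 6 NZW/LacJ arrays with consecutive sample numbers entered as a term, 1 on these arrays and 0 on all others, with all arrays and without those 2. Figures were drawn with matplotlib.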

Results

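The series measured gene expression in lung tissue of mice after 6 months of cigarette smoke or filtered air, in 4 strain or genotype units. Its title names emphysema models and human COPD; the human samples are not analysed here. C57BL/6J wild type had 22 air and 28 smoke arrays, Hhip+/- 12 and 14, Fam13a-/- 6 and 13, and NZW/LacJ 8 and 6. Hhip, an inhibitor of Hedgehog ligands, and Fam13a lie at COPD risk loci. The median share of probes detected per array ran from 48.6% in Fam13a-/- smoke to 51.1% in Fam13a-/- air. Values are normalized log2 signals, and differences are given on that scale with their standard errors.

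The probes of the targeted genes were read first. The Hhip probe (ILMN_2684250) measured 6.60 ± 0.34 (SD, n = 22) in C57BL/6J wild-type air and 6.55 ± 0.30 (SD, n = 12) in Hhip+/- air, a difference of -0.04 ± 0.14 (SE; limma adjusted p = 0.973). The Fam13a probe (ILMN_1224427) measured 6.12 ± 0.85 (SD, n = 22) in C57BL/6J wild-type air and 5.70 ± 0.33 (SD, n = 6) in Fam13a-/- air, a difference of -0.42 ± 0.36 (SE; limma adjusted p = 0.911), and 5 of those 6 arrays detected it. In smoke the Hhip probe measured 6.57 ± 0.48 (SD, n = 28) in C57BL/6J wild type and 6.54 ± 0.29 (SD, n = 14) in Hhip+/-. The Fam13a probe there measured 6.07 ± 0.69 (SD, n = 28) in C57BL/6J wild type and 5.44 ± 0.50 (SD, n = 13) in Fam13a-/-. No Fam13a-/- array read above 6.22, while C57BL/6J wild-type arrays reached 7.51 in air and 7.26 in smoke. Whether either probe lies in the deleted part is not known here, so these values check neither label, and Hhip+/- and Fam13a-/- below mean arrays so labelled.

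In 14 arrays labelled NZW/LacJ, probes that separate the strains were read in the same way. On genes lower in NZW/LacJ, 12 arrays lay between 0.85 and 1.11 on a scale from 0 (C57BL/6J) to 1 (NZW/LacJ). Air replicate 5 lay at 0.08 and smoke replicate 5 at 0.04, inside the ranges of C57BL/6J wild type, -0.05 to 0.09 in air and -0.07 to 0.06 in smoke. H2-Ea, an MHC class II gene, read 4.37 and 4.74 on these 2 arrays and at least 9.09 on the other 12. Both stay in the groups their labels give, and results for NZW/LacJ are also given without them, as an alternative chosen after seeing the data. Air replicate 5 also read 7.64 for Nqo1 and 9.36 for Cyp1b1, above every C57BL/6J wild-type air array (at most 6.88 and 7.75) and every other NZW/LacJ air array (at most 6.21 and 8.74). Its exposure label is therefore in doubt too, and was not tested.

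Among the NZW/LacJ arrays, 6 carry consecutive sample numbers: air replicates 3 and 4 and smoke replicates 1 to 4. Fam13a read 8.29 to 8.98 on these, and at most 7.23 on the other NZW/LacJ air arrays not doubted for strain and 5.68 on smoke replicate 6. As 2 of 8 air and 4 of 6 smoke arrays are in this set, exposure is partly confounded with it. Alternatives with the consecutive arrays as a term were also chosen after seeing the data. Without the 2 arrays doubted for strain, 5 air arrays and 1 smoke array, replicate 6, are left outside the set. That smoke array also lies below the bound for doubtful quality.

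**Figure D1:**
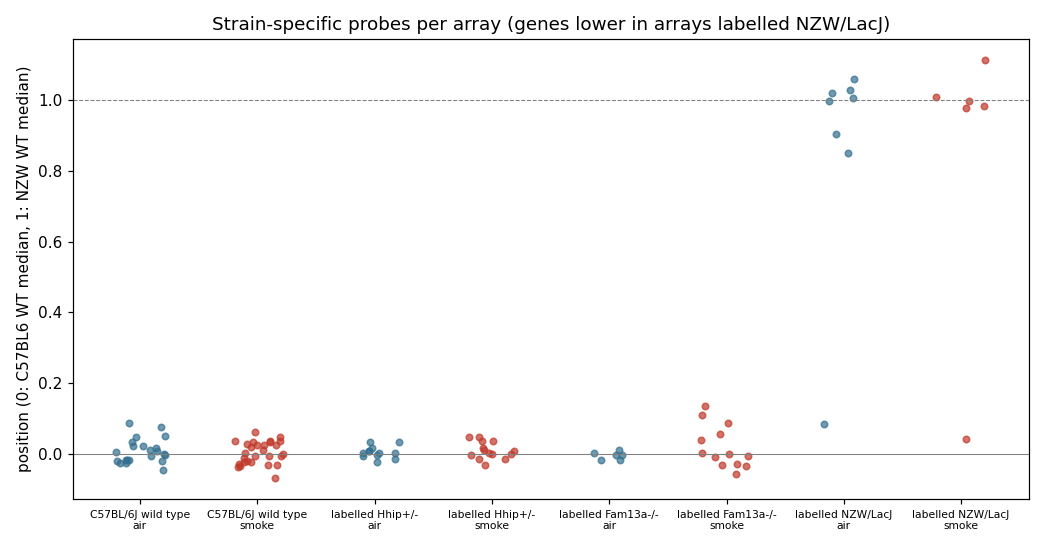
Position of each array (vertical axis, no unit; 0 is the C57BL/6J wild-type median, 1 the NZW/LacJ median) on genes lower in NZW/LacJ, by group, with air in blue and smoke in red. Of the arrays labelled NZW/LacJ, 12 lie between 0.85 and 1.11, and 1 air and 1 smoke array lie at 0.08 and 0.04.

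The first comparison asks what 6 months of smoke did in C57BL/6J wild-type lung. Among the largest rises were those of enzymes that handle smoke constituents and oxidants. Cyp1b1, a cytochrome P450 induced through the aryl hydrocarbon receptor (AhR), rose 7.76-fold, by 2.96 ± 0.29 (SE, n = 28 smoke and 22 air arrays; adjusted p = 1.09e-13), and was above the air mean in 26 of 28 smoke arrays. Nqo1, a quinone reductase, rose 4.77-fold, by 2.25 ± 0.20 (adjusted p = 5.91e-16), in 28 of 28 arrays. Slc7a11, the cystine transporter that feeds glutathione synthesis, rose 5.04-fold, by 2.33 ± 0.34 (adjusted p = 4.52e-07), and Aldh3a1, an aldehyde dehydrogenase, 3.87-fold, by 1.95 ± 0.21 (adjusted p = 2.04e-12). Cbr3, a carbonyl reductase, rose 3.22-fold with the smallest adjusted p among the genes named here (1.69 ± 0.12, adjusted p = 7.21e-22).

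Further rises were those of Adh7, an alcohol dehydrogenase (3.13-fold), the aldo-keto reductase Akr1b8 (2.74-fold), the carboxylesterase Ces1f (2.39-fold), Artn, a ligand of the GDNF family (2.36-fold), and Ugt1a6a, a glucuronosyltransferase (2.18-fold). Cyp1a1, the classical AhR target, and the glutathione transferase Gsta1 were detected on no air array, and on 20 and 23 of 28 smoke arrays. They were at least 1.74-fold and at least 1.51-fold higher with smoke (adjusted p = 3.19e-11 and 0.0025).

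The falls were smaller. Spon2, a secreted matrix protein with a role in innate immunity, fell by 1.15 ± 0.23 (adjusted p = 0.000732), below the air mean in 26 of 28 smoke arrays. Rptn fell by 0.79, Lrrc26 by 0.58, Got1l1 by 0.52, Cdh16, a cadherin, by 0.49, Noxa1, an activator of NADPH oxidase, by 0.49, Depp1 by 0.45 and Slc41a3, a magnesium transporter, by 0.40, with adjusted p from 0.00214 to 0.0355. Noxa1 was detected on 3 of 28 smoke and 11 of 22 air arrays. Hhip differed by -0.03 ± 0.11 (adjusted p = 0.982) and Fam13a by -0.05 ± 0.22 (adjusted p = 0.988).

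By gene list, 14 of 24 measured genes of the NRF2 and glutathione list rose and 0 fell (18 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 1.96e-60; adjusted p = 2.51e-11 with an estimated correlation). Of 7 measured AhR targets, 6 rose, over all genes and adjusted over the list alone, with a median of 1.87 (camera adjusted p = 3.93e-48; adjusted p = 9.68e-17 with an estimated correlation). Extracellular matrix genes had a median of -0.14, with 0 of 27 past the threshold over all genes and 2 lower adjusted over the list alone (camera adjusted p = 4.1e-06; adjusted p = 0.347 with an estimated correlation). Dendritic cell markers had a median of -0.20, with 0 of 10 past the threshold and 3 lower adjusted over the list alone (camera adjusted p = 0.00428; adjusted p = 0.201 with an estimated correlation). MHC class II genes and T and NK cell markers had medians of -0.17 and -0.14, with 0 members past the threshold either way (camera adjusted p = 0.0215 for both; adjusted p = 0.879 for both with an estimated correlation). In the list of type 1 alveolar epithelium, Igfbp2, an insulin-like growth factor binding protein, rose by 0.47 ± 0.11 and 9 of 10 members did not pass (camera adjusted p = 0.0181; adjusted p = 0.694 with an estimated correlation).

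In all, 92 genes rose and 16 fell of 11346 tested by limma, and 929 had an unadjusted p under 0.05. The residuals of the fit set 27 of the 107 arrays apart that were not doubted for strain, 6 of the 22 air and 8 of the 28 smoke arrays of this unit among them. Within those 14 arrays 7 genes were called and within the other 36 there were 91, with 7 and 71 of the 108 among them. Nqo1 rose by 2.32 and 2.23 in the 2 parts, and Cyp1b1 by 2.40 and 3.19.

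**Figure D2:**
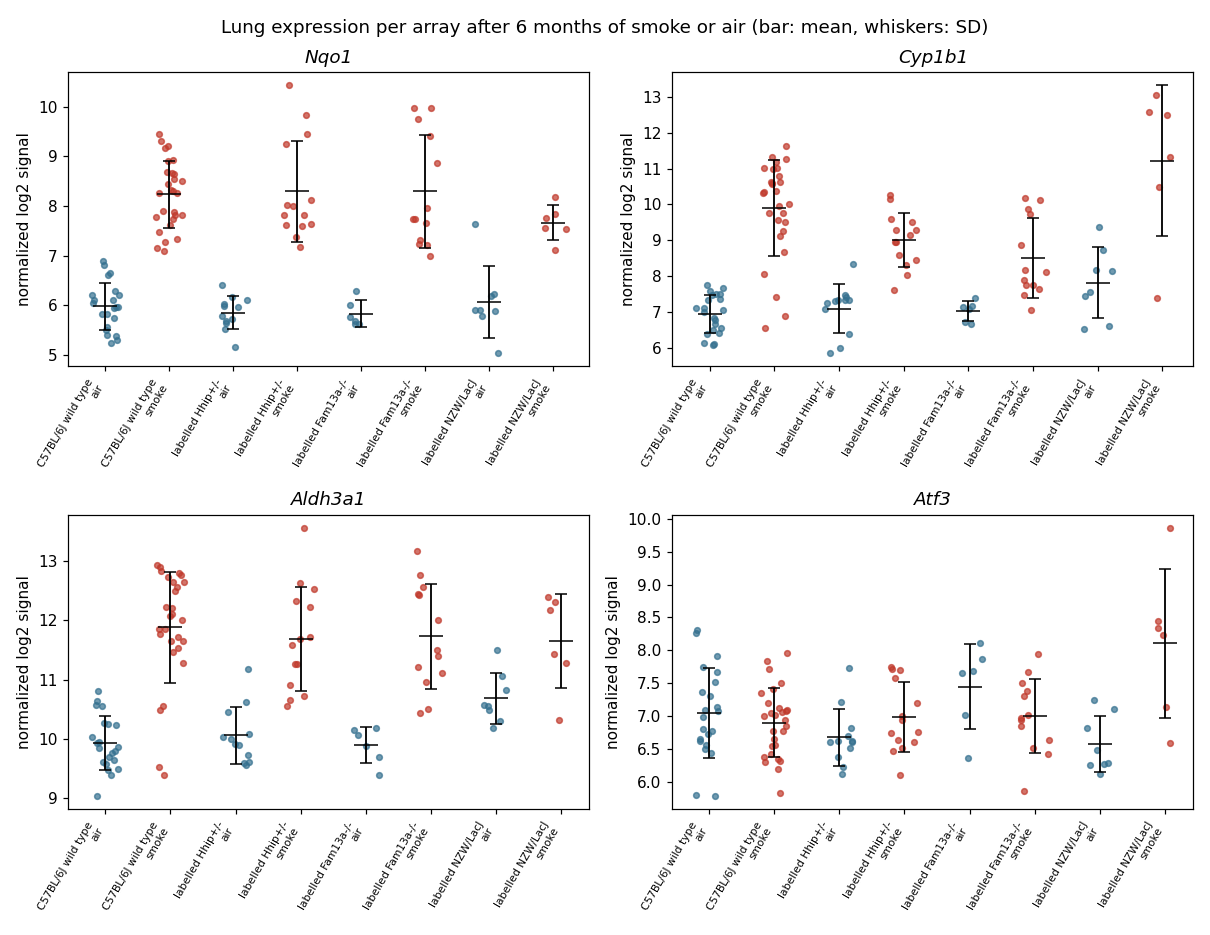
Normalized log2 signal (vertical axis) of Nqo1, Cyp1b1, Aldh3a1 and Atf3 on each array, by group, with air in blue and smoke in red; the bar is the mean and the whiskers the SD. Nqo1 averaged 5.98 in C57BL/6J air and 8.23 in smoke, and Atf3 averaged 6.57 and 8.10 in the arrays labelled NZW/LacJ.

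The next comparison asks what smoke did in lungs of mice labelled Hhip+/-. The same kind of enzymes led. Nqo1 rose 5.45-fold, by 2.45 ± 0.28 (SE, n = 14 smoke and 12 air arrays; limma adjusted p = 2.85e-10), above the air mean in 14 of 14 arrays. Cyp1b1 rose by 1.91 ± 0.40 (adjusted p = 0.00543), Aldh3a1 by 1.63 ± 0.29 (adjusted p = 0.000132), Akr1b8 by 1.48 ± 0.20 (adjusted p = 1.07e-07), and Gpx2, a glutathione peroxidase, by 1.07 ± 0.17 (adjusted p = 1.21e-05). Gsta1, detected on 10 of 14 smoke and 0 of 12 air arrays, was at least 1.88-fold higher (adjusted p = 0.0494).

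Retnla, a secreted marker of alternatively activated macrophages, rose 3.45-fold (1.79 ± 0.36, adjusted p = 0.00251), in 14 of 14 arrays. Npr3, the clearance receptor of natriuretic peptides, fell by 1.11 ± 0.25 (adjusted p = 0.0117), Map3k6, a stress kinase, by 0.95 ± 0.24 (adjusted p = 0.0494), and Fkbp14, a collagen chaperone, by 0.78 ± 0.19 (adjusted p = 0.0476). Hhip differed by -0.02 ± 0.15 and Fam13a by -0.17 ± 0.31 (adjusted p = 1 for both).

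Of the NRF2 and glutathione list, 6 of 24 genes rose (13 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 1.16e-33; adjusted p = 5.4e-07 with an estimated correlation). Of 7 AhR targets, 4 rose, Ugt1a6a among them by 0.94 ± 0.23, over all genes and adjusted over the list alone (camera adjusted p = 3.9e-18; adjusted p = 1.14e-07 with an estimated correlation). Genes of lysosomes and lipid-laden macrophages had a median of 0.12, with 0 of 23 past the threshold and 4 higher adjusted over the list alone (camera adjusted p = 5.73e-06; adjusted p = 0.241 with an estimated correlation). Chemokines and cytokines had a median of 0.09 and cell cycle genes one of 0.18, with 0 of 33 and 0 of 17 past the threshold and 1 and 0 higher adjusted over the list alone (camera adjusted p = 0.0127 and 0.0159; adjusted p = 0.801 and 0.821 with an estimated correlation). Glucocorticoid-responsive genes had a median of -0.25 and 2 of 11 lower adjusted over the list alone, and fatty acid oxidation genes a median of -0.07 and 0 of 18 (camera adjusted p = 0.0184 and 0.0429; adjusted p = 0.801 and 0.335 with an estimated correlation). Endothelial markers had a median of -0.11 with 0 of 21 past the threshold over all genes, while 1 was higher adjusted over the list alone (camera adjusted p = 0.0172; adjusted p = 0.801 with an estimated correlation). In all, 23 genes rose and 5 fell, and without air replicate 5 limma called 18.

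Smoke in lungs labelled Fam13a-/- was compared next. Nqo1 rose 5.52-fold, by 2.47 ± 0.35 (SE, n = 13 smoke and 6 air arrays; limma adjusted p = 6.04e-07), above the air mean in 13 of 13 arrays. Slc7a11 rose by 2.16 ± 0.59 (adjusted p = 0.0312), Aldh3a1 by 1.83 ± 0.36 (adjusted p = 0.000838), Akr1b8 by 1.60 ± 0.25 (adjusted p = 4.57e-06) and Gpx2 by 1.39 ± 0.21 (adjusted p = 4.13e-06). The largest rise was that of Gp2, a GPI-anchored glycoprotein that binds bacteria, at 3.26 ± 0.72 (adjusted p = 0.00498); Reg3g, an antibacterial lectin, rose by 2.50 ± 0.73 (adjusted p = 0.0446), and Gtsf1l by 2.13 ± 0.43 (adjusted p = 0.0013). Gp2 was detected on 12 of 13 smoke and 3 of 6 air arrays, Reg3g on 11 and 2.

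Aplnr, the apelin receptor, fell by 0.92 ± 0.25 (adjusted p = 0.0312), Pdgfrb, the PDGF receptor of pericytes, by 0.85 ± 0.24 (adjusted p = 0.0382), and Mfap4, a protein of elastic fibres, by 0.84 ± 0.23 (adjusted p = 0.0287). Pknox2 fell by 0.86, Tmcc2 by 0.82 and Dctn1, a dynactin subunit whose air values spread widely (7.73 ± 1.78, SD, n = 6), by 1.87 ± 0.55 (limma adjusted p = 0.0164, 0.0344 and 0.044). None of the 3 other kept probes of Pknox2 passed (0.05, -0.15 and 0.14). Hhip differed by -0.22 ± 0.19 (adjusted p = 0.621) and Fam13a by -0.26 ± 0.38 (adjusted p = 0.792).

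By list, 7 of 24 NRF2 and glutathione genes rose (11 adjusted over the list alone; camera adjusted p = 1.56e-12; adjusted p = 0.00762 with an estimated correlation). Of 7 AhR targets 3 rose (4 adjusted over the list alone), Ugt1a6a by 1.45 ± 0.29 (camera adjusted p = 4.21e-08; adjusted p = 0.00143 with an estimated correlation). Endothelial markers had a median of -0.36: 3 of 21 fell (6 adjusted over the list alone), among them Sox17, an endothelial transcription factor, by 0.69 ± 0.17 and Tek, the angiopoietin receptor, by 0.51 ± 0.15 (camera adjusted p = 6.93e-07; adjusted p = 0.12 with an estimated correlation). Ciliated cell markers had a median of 0.50: Ccdc39, needed for ciliary motility, rose by 0.74 ± 0.22, 13 of 14 did not pass over all genes, and 7 were higher adjusted over the list alone (camera adjusted p = 1.32e-06; adjusted p = 0.173 with an estimated correlation). Club and secretory cell markers had a median of 0.31, with Reg3g the 1 of 16 past the threshold and 4 adjusted over the list alone (camera adjusted p = 0.00151; adjusted p = 0.173 with an estimated correlation). Heart muscle genes, whose source in these samples is not known, had a median of 1.03 with 0 of 13 past the threshold either way (camera adjusted p = 7.57e-06, and 0.471 with an estimated correlation).

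Oxidative phosphorylation genes had a median of 0.16, with Atp5g1, an ATP synthase subunit, the 1 of 33 past the threshold (0.51 ± 0.13) and 8 adjusted over the list alone (camera adjusted p = 3.35e-06; adjusted p = 0.173 with an estimated correlation). Fatty acid oxidation genes had a median of 0.18 with 0 of 18 past the threshold either way (camera adjusted p = 0.00119; adjusted p = 0.0437 with an estimated correlation). Adipocyte markers had a median of 0.57 with 0 of 7 past the threshold and 5 adjusted over the list alone, and B cell markers a median of -0.46 with 0 of 11 (camera adjusted p = 7.4e-05 and 0.00633; adjusted p = 0.0719 and 0.741 with an estimated correlation).

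In all, 149 genes rose and 98 fell, 60.3% rising, against 186 and 57, or 76.5%, with median scaling. Without air replicate 1, 2, 3, 5 or 6, limma called 80, 68, 161, 118 or 127 genes. In a fit of this unit alone 215 genes were called, while 100 draws of 6 air and 13 smoke arrays of C57BL/6J wild type gave a median of 13 and at most 102.

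In the arrays labelled NZW/LacJ, smoke raised AhR targets most. Cyp1b1 rose by 3.41 ± 0.56 (SE, n = 6 smoke and 8 air arrays; limma adjusted p = 8.77e-05), above the air mean in 5 of 6 arrays, and Ahrr, the AhR repressor, by 1.36 ± 0.25 (adjusted p = 0.00082). Without the 2 arrays doubted for strain Cyp1b1 rose by 4.40 ± 0.55 (adjusted p = 1.1e-08). Ahrr and Cyp1a1, then detected on no air array, were at least 2.64-fold and at least 2.47-fold higher (adjusted p = 7.18e-07 and 7.96e-05). With all arrays Cyp1a1 rose by 1.64 ± 0.40 (adjusted p = 0.0244), Nqo1 by 1.60 ± 0.38 (adjusted p = 0.0189), Txnrd1, a thioredoxin reductase, by 1.52 ± 0.35 (adjusted p = 0.0123), and Cbr3 by 0.82 ± 0.23 (adjusted p = 0.0484).

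The stress and immediate early transcription factors Atf3 and Egr1 rose by 1.53 ± 0.32 (adjusted p = 0.00531) and 1.51 ± 0.38 (adjusted p = 0.0304), each in 6 of 6 arrays, and Errfi1, a feedback inhibitor of EGF receptors, by 0.86 ± 0.22 (adjusted p = 0.0368). Sox7, an endothelial transcription factor, fell by 1.18 ± 0.26 (adjusted p = 0.00976), Flrt2 by 0.93 ± 0.25 (adjusted p = 0.0396) and Fam180a by 0.91 ± 0.22 (adjusted p = 0.0232). Further falls were those of Rarg, a retinoic acid receptor, by 0.90 ± 0.24 (adjusted p = 0.0418; another kept probe -0.13, adjusted p = 0.75), the histone gene H2bc6 by 0.88 ± 0.22 (adjusted p = 0.032), Hs3st1, a heparan sulfate sulfotransferase, by 0.81 ± 0.21 (adjusted p = 0.0367) and the Hedgehog ligand Shh by 0.59 ± 0.15 (adjusted p = 0.0367). Without the 2 arrays Hs3st1 no longer passed (-0.73 ± 0.23, adjusted p = 0.059). Hhip differed by -0.56 ± 0.21 (adjusted p = 0.219) and Fam13a by 0.50 ± 0.42 (adjusted p = 0.635). With the consecutive arrays as a term Fam13a changed sign, to -0.63 ± 0.38, and to -0.54 ± 0.43 without the 2 doubted arrays as well (adjusted p = 1 and 0.907).

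Of 7 AhR targets, 4 rose (6 adjusted over the list alone; camera adjusted p = 1.39e-10; adjusted p = 8.7e-05 with an estimated correlation). Of 24 NRF2 and glutathione genes, 3 rose (8 adjusted over the list alone; camera adjusted p = 1.69e-08; adjusted p = 0.0716 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.32, with Errfi1 the 1 of 11 that rose and 2 adjusted over the list alone, and immediate early and heat shock genes one of 0.15, with Atf3 and Egr1 the 2 of 19 that rose and 5 adjusted over the list alone (camera adjusted p = 0.000199 and 0.00443; adjusted p = 0.286 and 0.66 with an estimated correlation). Of 5 Hedgehog genes Shh fell (2 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.0224; adjusted p = 0.286 with an estimated correlation). Interferon-responsive genes, oxidative phosphorylation genes and heart muscle genes had medians of 0.21, 0.04 and 0.53, with 0 of 21, 0 of 33 and 0 of 13 past the threshold either way (camera adjusted p = 0.0152, 0.0152 and 0.0224; adjusted p = 0.667, 0.811 and 0.918 with an estimated correlation). The oxidative phosphorylation and heart muscle lists no longer passed without the 2 doubted arrays (camera adjusted p = 0.472 and 0.204).

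In all, 60 genes rose and 52 fell, 53.6% rising, against 68.2% of 22 calls with median scaling and 66.7% of 159 with the authors' log2 values. Limma called 288 without the 2 doubted arrays, but 0 when only the NZW/LacJ arrays entered the fit, and single arrays left out moved the count from 13 to 696.

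With the consecutive NZW/LacJ arrays as a term 11 genes were called, 72.7% rising, with 7 of the 112 among them. Without the 2 doubted arrays as well there were 36, 80.6% rising, with 23 of the 112 among them. Outside the consecutive set that fit holds 1 smoke array, replicate 6, which is of doubtful quality. Of the genes named for smoke in this unit, Cyp1b1 (2.55 ± 0.58), Atf3 (1.52 ± 0.35) and Errfi1 (1.06 ± 0.24) passed with the term alone (adjusted p = 0.0443 for each). Cyp1a1 (1.43 ± 0.44), Nqo1 (1.67 ± 0.42), Ahrr (1.10 ± 0.27) and Sox7 (-1.08 ± 0.29) stayed nearly as large with the term but did not pass (adjusted p = 0.305, 0.0745, 0.0598 and 0.124). They passed without the 2 doubted arrays as well (adjusted p = 0.00697, 0.0156, 0.00119 and 0.0264). Txnrd1, Egr1, Flrt2, Fam180a, Rarg, H2bc6, Hs3st1, Cbr3 and Shh passed in neither. Among these, Fam180a (-0.90 ± 0.24), Hs3st1 (-0.84 ± 0.23) and Cbr3 (0.76 ± 0.25) kept about their size with the term. Egr1 (1.19 ± 0.41), Flrt2 (-0.71 ± 0.27) and H2bc6 (-0.69 ± 0.24) were somewhat smaller, and Txnrd1 (0.37 ± 0.28), Rarg (-0.35 ± 0.23) and Shh (-0.39 ± 0.16) shrank more. The AhR and NRF2 lists passed with the term (camera adjusted p = 1.41e-12 and 4.14e-11; adjusted p = 1.64e-05 and 0.0247 with an estimated correlation). The interferon list did not (camera adjusted p = 0.711; adjusted p = 0.958 with an estimated correlation). Without the 2 arrays as well, the NRF2 list passed only at the preset correlation (camera adjusted p = 2.64e-09; adjusted p = 0.0723 with an estimated one), and the Hedgehog list did not pass either way (camera adjusted p = 0.128; adjusted p = 0.607).

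**Figure D3:**
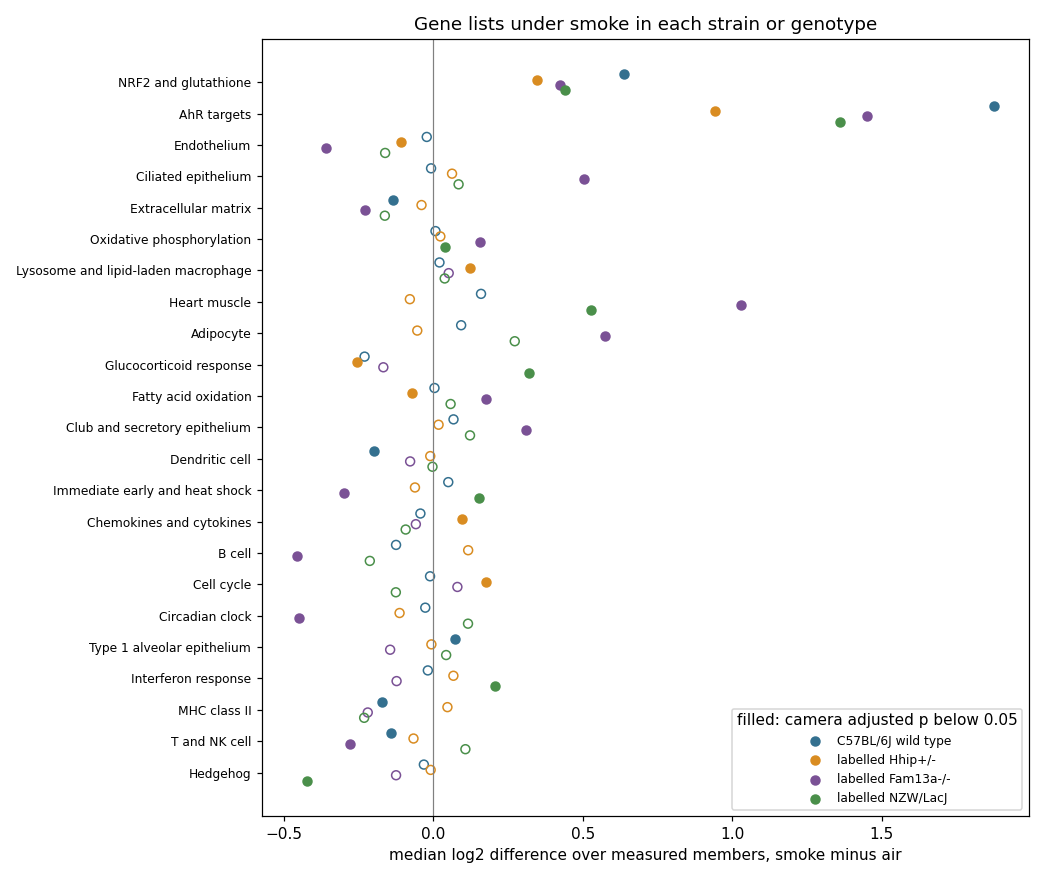
Median log2 difference of smoke minus air over the measured members of each gene list (horizontal axis), coloured by strain or genotype; filled points have a camera adjusted p below 0.05 at the preset correlation, and every list with such a point is drawn. AhR targets had medians of 1.87 in C57BL/6J wild type, 0.94 in Hhip+/-, 1.45 in Fam13a-/- and 1.36 in NZW/LacJ, and NRF2 and glutathione genes 0.64, 0.35, 0.42 and 0.44.

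The smoke effects of the 4 units, which share no arrays, were set against each other. Acox2, a peroxisomal oxidase, Cbr3, Ces1f, Nqo1 and the glucuronosyltransferase Ugt1a10 were called in all 4; Acox2 and Ugt1a10 are named after their values were seen, as members of this group of 5. With the consecutive NZW/LacJ arrays as a term, Cbr3 (0.76 ± 0.25) and Nqo1 (1.67 ± 0.42) kept about their size in NZW/LacJ but no longer passed (adjusted p = 0.411 and 0.0745). C57BL/6J wild type shared 20 rising genes with Hhip+/-, against 0.19 for independent lists of these lengths, 35 with Fam13a-/- (1.21) and 11 with NZW/LacJ (0.49). Hhip+/- shared 19 with Fam13a-/- (0.30) and 7 with NZW/LacJ (0.12), and Fam13a-/- shared 7 with NZW/LacJ (0.79). C57BL/6J wild type and Fam13a-/- shared 1 falling gene (0.14), and every other pair 0. Called in opposite directions were 1 gene between C57BL/6J wild type and NZW/LacJ, 2 between Fam13a-/- and NZW/LacJ, and 0 in the other pairs. The correlation of log2 differences across all genes, which are not independent replicates, was 0.34 between C57BL/6J wild type and Hhip+/-, 0.29 with Fam13a-/- and 0.12 with NZW/LacJ.

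Whether the smoke effect differed between Hhip+/- and C57BL/6J wild type was tested directly. Limma called 0 genes, and 491 had an unadjusted p under 0.05. With array weights it called 25. Of 39 gene lists 8 passed at the preset correlation and 0 with an estimated one. AhR targets had a median difference of -0.32, with 0 of 7 past the threshold and 2 lower adjusted over the list alone (camera adjusted p = 0.00303; adjusted p = 0.172 with an estimated correlation). Chemokines and cytokines had a median of 0.25, genes of lysosomes and lipid-laden macrophages 0.15, MHC class II genes 0.22 and neutrophil markers 0.27, with 0 members past the threshold either way (camera adjusted p = 0.00303, 0.00303, 0.0223 and 0.0429; adjusted p = 0.722, 0.65, 0.828 and 0.845 with an estimated correlation). Hhip differed by 0.02 ± 0.19 and Fam13a by -0.12 ± 0.38 (adjusted p = 1 for both).

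The smoke effect in Fam13a-/- differed from that in C57BL/6J wild type for 6 genes, 3 in each direction, or 2 higher and 4 lower with the authors' log2 values. Tmem204, an endothelial membrane protein, differed by -0.71 ± 0.13 (SE; limma adjusted p = 0.00464), Myh9, a non-muscle myosin, by -0.72 ± 0.15 (adjusted p = 0.0231) and Hdac5, a histone deacetylase, by -0.68 ± 0.15 (adjusted p = 0.0481). Gdpd2, a phosphodiesterase, differed by 1.27 ± 0.27 (adjusted p = 0.027) and C1rl, a complement-like protease, by 0.80 ± 0.18 (adjusted p = 0.0481), while another kept probe of C1rl gave -0.23 (adjusted p = 0.672). Fam13a itself differed by -0.21 ± 0.44 (adjusted p = 0.903) and Hhip by -0.19 ± 0.22 (adjusted p = 0.809). Ciliated cell markers had a median of 0.42, with 0 of 14 past the threshold and 1 higher adjusted over the list alone, endothelial markers -0.27, with 0 of 21 and 3 lower, and circadian clock genes -0.41, with 0 of 13, 1 higher and 5 lower (camera adjusted p = 1.28e-05, 0.000112 and 0.00648; adjusted p = 0.332, 0.332 and 0.295 with an estimated correlation). Heart muscle genes had a median of 0.90, with 0 of 13 either way (camera adjusted p = 0.000295; adjusted p = 0.633 with an estimated correlation). Of 39 lists 9 passed at the preset correlation and 0 with an estimated one. Median scaling moved the median of all genes in this comparison from -0.02 to 0.09. Single arrays left out moved the count from 1, without air replicate 1 or 2 or smoke replicate 11, to 19, without smoke replicate 3 or 10.

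The smoke effect in the arrays labelled NZW/LacJ differed from that in C57BL/6J wild type for 47 genes, 20 higher and 27 lower. Shh differed by -0.96 ± 0.17 (SE; limma adjusted p = 0.00261), Sox7 by -1.42 ± 0.30, Hhex, a homeobox gene, by -0.90 ± 0.19 (adjusted p = 0.0126 for both), Avil, an actin-binding protein, by -1.10 ± 0.24 (adjusted p = 0.014) and Hs3st1 by -1.07 ± 0.24 (adjusted p = 0.0177). Per1, a circadian clock gene that glucocorticoids induce, differed by 1.18 ± 0.23 (adjusted p = 0.00591). Errfi1 differed by 1.22 ± 0.25, Atf3 by 1.68 ± 0.36 and Slc35f5 by 1.06 ± 0.23 (adjusted p = 0.0126 for each); Slc35f5 was detected on 4 of 6 smoke and 2 of 8 air arrays of this unit. The effect on Ptgs2, the inducible cyclooxygenase, was called higher (adjusted p = 0.0126). It was detected on 4 of 6 smoke and 0 of 8 air arrays, and on no C57BL/6J wild-type air array, so no size is given. Hhip differed by -0.53 ± 0.24 (adjusted p = 0.38) and Fam13a by 0.55 ± 0.48 (adjusted p = 0.689). With the consecutive arrays as a term Fam13a changed sign here too, to -0.58 ± 0.42, and to -0.49 ± 0.47 without the 2 doubted arrays as well (adjusted p = 1 and 0.88).

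Glucocorticoid-responsive genes had a median difference of 0.50, with Errfi1 the 1 of 11 past the threshold and 6 adjusted over the list alone (camera adjusted p = 2.38e-05; adjusted p = 0.373 with an estimated correlation). Immediate early and heat shock genes had a median of 0.26, with Atf3 the 1 of 19, and 6 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0385; adjusted p = 0.984 with an estimated correlation). Of 5 Hedgehog genes Shh was lower, also adjusted over the list alone (camera adjusted p = 0.0361; adjusted p = 0.373 with an estimated correlation). The immediate early and Hedgehog lists no longer passed without the 2 doubted arrays (camera adjusted p = 0.0704 for both), while 199 genes were called, 44 of the 47 among them. With median scaling 12 were called, 25% of them higher against 42.6% of the 47, and in a fit of the 4 groups alone 2. Single arrays left out moved the count from 1 to 429.

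With the consecutive NZW/LacJ arrays as a term 5 genes differed, all among the 47, and Per1, Errfi1 and Hhex were the named ones (adjusted p = 0.0113, 0.00849 and 0.0113). Without the 2 doubted arrays as well there were 18, 72.2% higher, with 9 of the 47 among them, and Atf3 and Sox7 passed too (adjusted p = 0.00866 and 0.0214). Atf3 (1.67 ± 0.39), Sox7 (-1.32 ± 0.32), Hs3st1 (-1.10 ± 0.26) and Avil (-1.02 ± 0.26) kept about their size with the term (adjusted p = 0.0567, 0.0736, 0.0567 and 0.103). Shh differed by -0.76 ± 0.18 (adjusted p = 0.0613) and by -0.80 ± 0.20 without the 2 arrays as well (adjusted p = 0.0535), while Slc35f5 shrank to 0.31 ± 0.15 with the term (adjusted p = 0.994). Ptgs2, Slc35f5, Avil, Hs3st1 and Shh passed in neither. The glucocorticoid list passed in both at the preset correlation only (camera adjusted p = 1.83e-08 and 2.9e-05; adjusted p = 0.0777 and 0.541 with an estimated correlation). The immediate early list passed in neither (camera adjusted p = 0.0502 and 0.151; adjusted p = 0.793 and 0.852 with an estimated correlation).

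Hhip+/- and C57BL/6J wild type were compared in air. Wild-type air replicates 6 and 22, whose genotype labels are questioned below, stayed in their group. Mt3, a metallothionein, was higher in Hhip+/- (a fitted 2.33 ± 0.31, SE, n = 12 and 22 arrays; limma adjusted p = 1.56e-07), above the wild-type mean in 12 of 12 arrays. It was detected on 12 of 12 and 2 of 22 arrays, and with the same lower limit on the wild-type signal as in the other bounds it was at least 3.47-fold higher. Ciapin1, an iron-sulfur cluster assembly factor, was higher by 0.39 ± 0.08 (adjusted p = 0.00683). Crem, a cAMP-responsive transcription factor, differed by -0.77 ± 0.15 (adjusted p = 0.00683), the zinc finger genes Zfp869 by -0.60 ± 0.10 (adjusted p = 0.000567) and Zfp930 by -0.54 ± 0.11 (adjusted p = 0.00836), Nmrk1, a nicotinamide riboside kinase, by -0.54 ± 0.11 (adjusted p = 0.00836), and Emcn, an endothelial sialomucin, by -0.43 ± 0.09 (adjusted p = 0.0132). Fam13a differed by 0.21 ± 0.28 (adjusted p = 0.896).

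Of 39 lists 5 passed at the preset correlation and 0 with an estimated one. These were the 7 genes called, 2 higher and 5 lower (28.6% higher). With no background correction 18 were called, 55.6% higher, with median scaling 12, 41.7% higher, and with the authors' log2 values 18, 61.1% higher. Plasma cell and immunoglobulin genes had a median of 0.28, B cell markers one of 0.16 and oxidative phosphorylation genes one of -0.09, with 0 members past the threshold and 1, 0 and 0 adjusted over the list alone (camera adjusted p = 0.0138, 0.0428 and 0.0138; adjusted p = 0.913 for each with an estimated correlation).

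Over both exposures, a contrast chosen after seeing the data, limma called 415 genes between Hhip+/- and C57BL/6J wild type, 181 higher and 234 lower. Wild-type air replicates 6 and 22 stayed in here too, and no fit without them is given. On chromosome 8, which carries Hhip in the GRCm38.p6 assembly, 53 of 563 genes were called (9.41%), against 3.36% of genes elsewhere (Fisher's exact p = 1.69e-10). Mt3 was higher by a fitted 2.20 ± 0.21 (SE, n = 26 and 50 arrays), Ssbp4 higher by 0.53 ± 0.08, Zfp330 lower by 0.90 ± 0.18, B3gnt3 lower by 0.70 ± 0.09 and Zfp869 lower by 0.66 ± 0.07; Zfp330, B3gnt3 and Ssbp4 are named after their values were seen. The Zfp330 value rests on the probe that differed by -4.43 in NZW/LacJ air, where another kept probe differed by only -0.48. The contrast over both exposures for Fam13a-/- called 95 genes, 6 of 540 on the chromosome of Fam13a (1.11%, against 0.82% elsewhere, Fisher's exact p = 0.462).

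**Figure D4:**
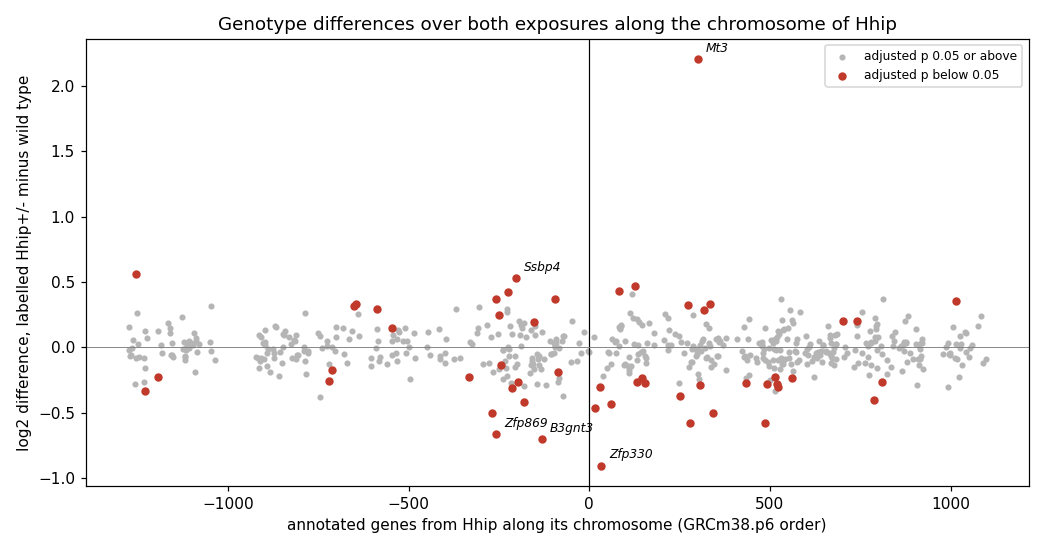
Log2 difference of Hhip+/- minus C57BL/6J wild type over both exposures (vertical axis) for the genes of the chromosome that carries Hhip, in gene order (horizontal axis, number of genes); red points have a limma adjusted p under 0.05. Of 563 genes, 53 were called.

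Between Fam13a-/- and C57BL/6J wild type in air, limma called 0 genes (n = 6 and 22 arrays), and 692 had an unadjusted p under 0.05; with array weights 321 were called and without air replicate 4 limma called 1. Hhip differed by -0.28 ± 0.18 (adjusted p = 0.856). Circadian clock genes had a median of 0.26 with 0 of 13 past the threshold and 4 higher adjusted over the list alone (camera adjusted p = 0.00242; adjusted p = 0.16 with an estimated correlation). Extracellular matrix genes had a median of -0.19 with 0 of 27 either way, immediate early and heat shock genes 0.27 with 0 of 19 and neutrophil markers 0.43 with 0 of 14 (camera adjusted p = 0.00242, 0.00394 and 0.0146; adjusted p = 0.857, 0.857 and 0.894 with an estimated correlation).

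The arrays labelled NZW/LacJ differed widely from C57BL/6J wild type in air. The largest positive differences were those of H2-Ea, at least 25.1-fold higher (limma adjusted p = 9.03e-24; n = 8 and 22 arrays), which no C57BL/6J air array detected, and the haemoglobin gene Hbb-b2 (4.70 ± 0.44, adjusted p = 1.72e-16). Psca, a GPI-anchored surface protein, was at least 13.1-fold higher (adjusted p = 1.12e-24), and Avpr1a, a vasopressin receptor, Ccdc190 and H2-Q5 were higher by 3.66 ± 0.30, 3.63 ± 0.26 and 3.12 ± 0.26. The largest negative ones were those of Fcer1g, the Fc receptor gamma chain (-5.63 ± 0.38), Chil3, a chitinase-like protein of alveolar macrophages (-5.40 ± 0.43), Sspn, sarcospan (-4.80 ± 0.35), Slpi, an inhibitor of leukocyte proteases (-4.61 ± 0.39), Abhd16a (-4.45 ± 0.30) and Zfp330 (-4.43 ± 0.31), each with an adjusted p of 4.71e-19 or lower. A probe over a strain variant can differ with no change in expression. Another kept probe of Zfp330 differed by only -0.48 (adjusted p = 0.000178) and one of Avpr1a by 2.06 (adjusted p = 1.65e-22), so the sizes for these 2 genes depend on the probe. Without the 2 doubted arrays the differences were larger: H2-Ea and Psca were at least 44.3-fold and at least 19.5-fold higher, Hbb-b2 was higher by 5.39 ± 0.35, and Fcer1g and Sspn differed by -6.28 ± 0.24 and -5.55 ± 0.17. Of the 7 NZW/LacJ air arrays left, 3 detected Fcer1g, 1 Sspn, 3 Abhd16a and 4 Zfp330. The sizes of these falls are therefore limited by signal near background.

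Markers of type 2 alveolar epithelium were lower: 12 of 16 (13 adjusted over the list alone), among them Lamp3 by -2.60 ± 0.29, Chia1, a chitinase, by -2.51 ± 0.25, Napsa, which processes surfactant protein B, by -2.45 ± 0.19, and Etv5 by -1.48 ± 0.17 (camera adjusted p = 1.5e-09; adjusted p = 0.0978 with an estimated correlation, and 0.0306 without the 2 doubted arrays). Of neutrophil markers 12 of 14 were lower, also adjusted over the list alone, including the calprotectin subunits S100a8 (-2.34 ± 0.36) and S100a9 (-2.10 ± 0.40), Retnlg (-2.05 ± 0.45) and the antimicrobial Camp (-1.81 ± 0.32). Of alveolar macrophage markers 6 of 8 were lower, also adjusted over the list alone, including Krt79 (-2.96 ± 0.29), the lipid droplet gene Cidec (-1.82 ± 0.23) and the mannose receptor Mrc1 (-0.84 ± 0.18). Camera adjusted p was 6.18e-05 and 6.35e-05 for these 2 lists (adjusted p = 0.507 and 0.168 with an estimated correlation).

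Of MHC class II genes 8 of 11 were lower (9 adjusted over the list alone), among them H2-DMb2 (-1.55 ± 0.30), H2-Oa (-1.35 ± 0.27), H2-DMa (-1.15 ± 0.15) and Cd74, the invariant chain (-0.87 ± 0.13). Of T and NK cell markers 8 of 16 were lower and 2 higher, with Nkg7 at -2.43 ± 0.29 and Cd8b1 at -1.72 ± 0.25. Of chemokines and cytokines 16 of 33 were lower and 3 higher (17 and 3 adjusted over the list alone), with Ccl6 at -2.59 ± 0.33, Ccl5 at -2.04 ± 0.29 and Csf1, the macrophage growth factor, at 1.99 ± 0.17. Of markers of monocytes and interstitial macrophages 6 of 12 were lower, with Plac8 at -0.97 ± 0.25 and Apoe at -0.80 ± 0.14. Camera adjusted p was 9.03e-05, 0.0013, 0.0013 and 0.00684 for these 4 lists (adjusted p = 0.507 for each with an estimated correlation).

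Of ciliated cell markers 13 of 14 were higher, also adjusted over the list alone, with Rsph1, a radial spoke protein, at 1.41 ± 0.17 and Dnaic1 at 0.90 ± 0.17, and of smooth muscle genes 8 of 9 were higher (9 adjusted over the list alone), with Pln, phospholamban, at 1.19 ± 0.29, Myh11 at 0.97 ± 0.19 and Actg2 at 0.92 ± 0.21 (camera adjusted p = 9.03e-05 and 0.00245; adjusted p = 0.507 for both with an estimated correlation). Of oxidative phosphorylation genes 15 of 33 were lower and 1 higher, with Atp5o at -0.68 ± 0.15 and Ndufs4 at -0.64 ± 0.11 (camera adjusted p = 0.00684; adjusted p = 0.507 with an estimated correlation). The other 3 kept probes of Ndufs4 gave -0.06, 0.28 and -0.32, none past the threshold (adjusted p = 0.817, 0.404 and 0.225). Hhip was higher by 0.95 ± 0.16 (adjusted p = 9.55e-07), above the C57BL/6J mean in 8 of 8 arrays, and Fam13a by 0.92 ± 0.32 (adjusted p = 0.0149), in 6 of 8. Without air replicates 3 and 4, and with doubted air replicate 5 kept, Hhip was higher by 0.82 ± 0.18 (adjusted p = 0.000135) and Fam13a by 0.33 ± 0.34 (adjusted p = 0.486). With the 2 doubted arrays left out instead, Hhip was higher by 1.04 ± 0.17 (adjusted p = 1.45e-07) and Fam13a by 1.16 ± 0.32 (adjusted p = 0.00149). The call of Fam13a thus depends on air replicates 3 and 4 when replicate 5 stays. No fit without these and replicate 5 is given. In all, 2809 genes were higher and 2099 lower. Without the 2 doubted arrays 5302 were called, and 5243 without the air one alone, which the choice of these arrays by strain-specific probes favours. Without both, the oxidative phosphorylation list no longer passed (camera adjusted p = 0.051).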

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

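The tests of what the 2 doubted arrays are, of Hedgehog signalling, of the arrays standing apart in Fam13a-/- and of single Fam13a-/- air arrays were chosen only after the result was seen, as were the fits and splits without the 2 doubted arrays and the fits and splits with the consecutive NZW/LacJ arrays as a term.

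In groups of 6 to 8 arrays, 18 of 125 gene and group pairs had an array far from the others, by its gap to the nearest array over the range of the group. Chance gives about 1 in 20, and 13 of the 18 were in a single array, NZW/LacJ air replicate 5. That array was highest for Cyp1a1 (6.80, ratio 0.941), Nqo1 (7.64, 0.546), Avil (6.74, 0.578), Slpi (10.24, 0.537), Abhd16a (10.17, 0.586) and Zfp330 (10.33, 0.542). It was lowest for H2-Ea (4.37, 0.629), Hbb-b2 (5.79, 0.759), Psca (5.20, 0.878), Avpr1a (5.72, 0.847), Ccdc190 (4.50, 0.610), H2-Q5 (4.61, 0.579) and Csf1 (7.32, 0.647). In the same group, air replicate 1 stood apart for Mrc1 (10.93, 0.542), Atp5o (8.38, 0.657) and Ndufs4 (11.55, 0.556), air replicate 3 for Hhip (8.45, 0.535) and air replicate 4 for Ptgs2 (5.27, 0.549).

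On strain-specific probes, air replicate 5 and smoke replicate 5 labelled NZW/LacJ read as C57BL/6J, and the air one also reads above every C57BL/6J wild-type air array for Nqo1 (7.64 against at most 6.88), so its exposure label is in doubt, untested. A mixture of RNA from both strains is argued against by H2-Ea, at most 4.74 on the 2 arrays and at least 9.09 on the other 12. A failed hybridization is argued against by the share of probes detected, 46.1% on the lower of the 2, within the 45.1% to 53.9% of the others. A swap with an array labelled C57BL/6J wild type needs a partner out of place, and the highest position among those arrays was 0.0878. What stays open is a wrong strain label, which may fit, since the higher of the 2 positions was 0.0832, within the C57BL/6J range; the strain difference itself gives no biological account of 2 such arrays, and none was tested.

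Genes on the chromosome of Hhip were called more often between Hhip+/- and C57BL/6J wild type than genes elsewhere. With the arrays standing apart in the residuals as a term, 52 of the 53 genes stayed called. That set was drawn from the residuals of the group means, so the term could hardly move these differences. That the genes stayed called was largely fixed in advance, and does not decide on the set as a cause. DNA around Hhip that came with the targeted allele, from another strain, may account for it: called genes lay a median of 302 genes from Hhip, others 562 (permutation p = 0.00043). Only 5 Hedgehog genes were measured, Hhip itself, Smo, Sufu, Shh and Disp1, and their list did not pass (camera p = 0.531). Ptch1 and Gli1, also in the list, were not among those measured. Hedgehog signalling raised by 1 copy of Hhip thus cannot be told apart from no change. An effect of Hhip dosage on these genes stays open, untested. Calls from probes over variants in DNA around Hhip, with no change in expression, were not tested either.

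The smoke effect in Fam13a-/- alone called 215 genes, against at most 102 in C57BL/6J draws of the same size. With the arrays standing apart as a term 247 of 247 called genes stayed called. As that set was drawn from the residuals of the group means, this was largely fixed in advance and decides nothing. In the arrays outside the set alone, 5 air and 9 smoke, 329 genes were called, with 114 of the 247 among them. A high count was thus also seen without the arrays of the set. Another share of airway tissue or heart muscle in the sample may account for part of the count. With the means of those lists as covariates, 45 of 245 genes stayed called. Their median absolute log2 change went from 0.62 to 0.47 while the median SE went from 0.168 to 0.156, and 245 kept their sign. At the median the changes thus shrank while the SE did not grow. With fewer genes called the adjustment is also stricter, and why each call ended was not tested. Without a single air array the lowest count was 47, though these fits have 5 air arrays and the draws 6; 4 of the 6 such fits gave 102 genes or fewer, and the genotype itself stays open, untested.

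The smoke effect differed from that of C57BL/6J wild type, by a direct test, for these named genes. In Fam13a-/- they were Tmem204 (-0.71), Myh9 (-0.72), Gdpd2 (1.27), C1rl (0.80) and Hdac5 (-0.68), and with the airway and heart list means as covariates 1 of the 6 called genes was still called, Tmem204 (-0.55). C1rl then kept its size (0.79 ± 0.19), and Myh9 (-0.62 ± 0.15), Hdac5 (-0.57 ± 0.16) and Gdpd2 (0.99 ± 0.27) were smaller. In the arrays labelled NZW/LacJ they were Shh (-0.96), Per1 (1.18), Errfi1 (1.22), Sox7 (-1.42), Hhex (-0.90), Ptgs2 (1.001, a fitted value that gives no size, as no air array of either wild-type group detected it), Atf3 (1.68), Slc35f5 (1.06), Avil (-1.10) and Hs3st1 (-1.07), and these 10 still passed without the 2 doubted arrays. With the consecutive NZW/LacJ arrays as a term only Per1, Errfi1 and Hhex passed, and Atf3 and Sox7 too without the 2 doubted arrays as well. With the term Atf3 (1.67), Sox7 (-1.32), Hs3st1 (-1.10) and Avil (-1.02) kept about their size though not the call, while Slc35f5 (0.31) shrank.

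Arrays were also split at random into groups of the same sizes, 100 splits with the real one. Fewer than 5 of 100 was taken to argue against chance, with no adjustment over the comparisons. For smoke in C57BL/6J wild type, 1 split gave as many genes (real 108, highest other 68), in Hhip+/- 2 (28 and 43) and in Fam13a-/- 1 (247 and 35). The air comparisons of Hhip+/- and NZW/LacJ had 1 each (7 and 1, 4908 and 1752). By that rule these 5 argue against chance, though the splits ignore the arrays set apart in the residuals. The difference of smoke effects in Fam13a-/- had 2 splits (6 and 81). As single arrays left out moved its count from 1 to 19, chance is not excluded there. Chance cannot be excluded for smoke in NZW/LacJ, with 37 splits (112 and 2033), nor without the 2 doubted arrays, with 24 (288 and 2485). For the differences of smoke effects, the splits redrew the strain or genotype label within each exposure and kept the exposure. In NZW/LacJ, 5 such splits gave as many genes (47 and 1062). They mix strains that differ in 4908 genes in air, and uneven mixes can themselves give calls. These splits thus cannot test chance for that difference, and chance is not excluded. Without the 2 arrays the difference had 4 (199 and 1351), with the same limit, and those splits also ignore the consecutive arrays. In the 90 splits that redraw exposure among NZW/LacJ arrays inside and outside that set, without the 2 arrays and with the set as a term, 11 gave as many genes for smoke (36 and 1278) and 36 for the difference (18 and 737). Chance is thus not excluded for either. For the difference in Hhip+/- and for Fam13a-/- air, where limma called 0 genes, all 100 splits gave as many (highest other 0 and 1). Splits that call many times the real count, as for smoke in NZW/LacJ and in the difference for Fam13a-/-, point to a structure of these samples, whose nature was not tested. In the difference for NZW/LacJ the splits mix the strains, which can give such counts.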

How the results depend on the processing

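The fits without the doubted arrays, without faint arrays, with the set apart or the consecutive NZW/LacJ arrays as a term, with unscaled deviations and without single arrays were chosen only after the result was seen. No named gene and no list described was called in the opposite direction. Among all genes, the mean of a gene's probes turned the sign of 85 of the 4908 NZW/LacJ air calls. Of 141 named results past the threshold, 109 stayed past it when only the compared groups were fitted, 117 with median scaling, 126 with no filter, 127 with the authors' log2 values, 131 with no background correction, 134 with the mean of a gene's probes, 140 with a variance trend, and 141 with array weights, with 2 residual components and without doubtful arrays. With the stricter filter 120 of the 126 still tested did. The 2 residual components come from the residuals of the same fit, so they leave each log2 difference unchanged and lower its residual spread. That named results stayed called with them was therefore largely fixed in advance. Of 75 list results, 61 to 75 stayed called under these alternatives, and 8 with an estimated correlation. With the consecutive arrays as a term 119 named results and 71 list results stayed, and 126 and 63 without the 2 doubted arrays as well. In each case below the cause was not tested.

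Array weights gave 187 genes for smoke in C57BL/6J wild type, 184 in Hhip+/-, 1631 in Fam13a-/- and 1856 in NZW/LacJ; 25, 726 and 1475 for the differences of smoke effects of Hhip+/-, Fam13a-/- and NZW/LacJ; and 276 and 321 for Hhip+/- and Fam13a-/- air. With 2 residual components these were 196, 93, 1124 and 1170, then 431 and 1001 for the differences of Fam13a-/- and NZW/LacJ, and 208 and 20 in air. With these components the log2 differences stay as they are and only their spread changes. For smoke in NZW/LacJ and its difference, median scaling gave 22 and 12, the stricter filter 28 and 31, the fit of only the groups compared 0 and 2, the fit without doubtful arrays 1221 and 959, the unscaled bound 1951 and 1502, the fit without the 2 doubted arrays 288 and 199, without faint arrays too 330 and 212, and with the set apart as a term 347 and 245; the authors' log2 values gave 72 for the difference. In the fits without doubtful arrays and with the unscaled bound, all NZW/LacJ smoke arrays left are consecutive, so the larger counts there come with stronger confounding. The set apart as a term gave 457 for smoke in Fam13a-/- and 28 for its difference, for which the unscaled bound gave 15. The correlation of smoke effects of Fam13a-/- and NZW/LacJ, 0.07, was -0.12 with the unscaled bound.

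The consecutive arrays as a term gave 11 genes for smoke in NZW/LacJ and 5 for its difference, and turned the sign of 5 of the 112 and of 17 of the 4908 air calls. Without the 2 doubted arrays as well these were 36, 18, 2 and 10, with 19 for the difference in Fam13a-/- and 21 for Hhip+/- air. The correlation of smoke effects of Fam13a-/- and NZW/LacJ was 0.36 with the term and 0.24 without the 2 arrays as well, where that of Hhip+/- and NZW/LacJ, 0.06, was 0.26.

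Hhip+/- air, with 7 genes, gave 18 with no background correction and with the authors' log2 values, 12 with median scaling, 19 with the mean of a gene's probes, 21 with only the groups compared, 16 with a variance trend, 22 without doubtful arrays, 32 with the unscaled bound, 19 without the 2 doubted arrays, 16 without faint arrays too, and 33 with the set apart as a term. Fam13a-/- air gave 1 with only the groups compared.

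Leaving out single arrays of the 3 smaller units gave, lowest and highest, 18 and 31 genes for smoke in Hhip+/-, 68 and 348 in Fam13a-/- and 13 and 696 in NZW/LacJ. The differences gave 0 and 0, 1 and 19, and 1 and 429, and the air comparisons 7 and 18, 0 and 1, and 4280 and 5243. Smoke in NZW/LacJ gave 18, 13, 14, 74, 614 and 696 without smoke replicates 1 to 6, 57, 324 and 300 without air replicates 2, 3 and 4, and 36 without air replicate 6 or 8. Its difference gave 4, 1, 4, 429 and 338 without smoke replicates 1, 2, 3, 5 and 6, and 22, 145, 152, 13 and 19 without air replicates 2, 3, 4, 6 and 8. The difference in Fam13a-/- gave 3 without air replicate 3 or smoke replicate 5 or 9, 2 without smoke replicate 13 and 12 without air replicate 5. Hhip+/- air gave 13, 14 and 11 without air replicates 1, 6 and 12, and 13, 13, 12, 13, 18, 13 and 14 without smoke replicates 3, 5, 7, 8, 9, 10 and 11. Draws of C57BL/6J wild-type arrays at the NZW/LacJ sizes gave a median of 9.5 genes, and of 6 with no filter on dim probes.

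No paired analysis was possible because the replicate numbers follow the order of deposit and link no air array to a smoke array. A Y-linked covariate and the slide as a block were not run. Arrays of C57BL/6J wild type were not left out singly. Signal near background limits folds: Cyp1a1 and Gsta1 are bounds in C57BL/6J wild type.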

Other observations

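The tests without the 2 doubted arrays and of the order of sample numbers, of called genes on the chromosome of Hhip, and the choice of the arrays described, were made only after the result was seen. Of the 108 genes called for smoke in C57BL/6J wild type, 98 had the same sign in Hhip+/-, 95 in Fam13a-/- and 91 in the arrays labelled NZW/LacJ. Over genes called in either unit, the correlation of log2 differences with C57BL/6J wild type was 0.83 in Hhip+/-, 0.56 in Fam13a-/- and 0.43 in NZW/LacJ; genes chosen for a change in one of the units raise such values.

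Without the 2 doubted arrays, smoke in NZW/LacJ gave Nqo1 a rise of 1.93 ± 0.40 (SE, n = 5 smoke and 7 air arrays), Atf3 one of 1.80 ± 0.34 and Txnrd1 one of 1.91 ± 0.33, and Shh a fall of 0.73 ± 0.16. The plasma cell and immunoglobulin list then had a median of -0.52 (camera adjusted p = 0.0154) and the MHC class II list one of -0.36 (camera adjusted p = 0.0269), neither called with these arrays in (adjusted p = 0.639 and 0.881 with an estimated correlation). The circadian clock list was called too, with a median of 0.23 (camera adjusted p = 0.0374; adjusted p = 0.401 with an estimated correlation), while the oxidative phosphorylation and heart muscle lists were lost.

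In Fam13a-/-, the mean over ciliated cell markers was 8.09 ± 0.20 (SD, n = 6) in air and 8.52 ± 0.34 (SD, n = 13) in smoke, and that over heart muscle genes 8.68 ± 1.02 and 9.87 ± 1.26. In C57BL/6J wild type they were 7.98 ± 0.28 and 7.96 ± 0.20, and 8.69 ± 1.199 and 8.82 ± 1.23.

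The 27 arrays standing apart in the residuals held 21 pairs of neighbouring sample numbers, against a median of 7 in shuffled order (permutation p = 1e-05, the smallest these permutations can give). The first residual component held 20.98% of the residual variance and the next 10.6%. A scale from wild type to Hhip+/- was read on genes of the chromosome of Hhip called in the other exposure, at any distance from Hhip. It held 36 genes for air arrays and 8 for smoke arrays. On this scale Hhip+/- air arrays ran from 0.35 to 1.14. The C57BL/6J wild-type air arrays had a median of 0.22, and 7 of 22 lay at 0.36 or higher. Mt3 was detected on 2 of these 7: replicate 6 (position 0.58, Mt3 7.92, Zfp869 8.49) and replicate 22 (0.81, 6.60 and 8.60). Replicate 8 (0.81) read 4.83 for Mt3 and 9.74 for Zfp869. Mt3 does not follow the labels on every array: Hhip+/- smoke replicates 1, 5 and 12 read 4.67, 5.40 and 4.83 at positions of 0.74, 0.71 and 0.69, and C57BL/6J wild-type smoke replicates 4 and 12 read 7.26 and 8.45 at 0.19 and 0.35. Whether the genotype labels of air replicates 6 and 22 are right stays open, untested. NZW/LacJ air replicate 6 read 8.08 for Fcer1g and 9.27 for Ctsc. H2-Ea read 8.03 on 1 C57BL/6J smoke array and at most 4.99 on the other C57BL/6J wild-type arrays. Xist was detected on 109 of 109 arrays.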
